A study of Caenorhabditis elegans with 2 samples.

How the data were processed

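Chromatin of whole L4 larvae was immunoprecipitated with an anti-GFP antibody from a strain with a tagged ceh-20 gene and sonicated, per the labels. There were 2 samples, labelled as biological replicates 1 and 2, and both belong to 1 group. Control libraries were not analysed here. All peak lists are on assembly ce11, per the deposited file descriptions, and were derived from the alignments of 1 library or of both together with a further file. The aligner, the peak caller and their versions were not given in the sources used here.

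The authors deposited lists ranked by the irreproducible discovery rate (IDR, a measure of how well peaks keep their rank between 2 inputs) and lists kept after a threshold on it. Each replicate has 1 list of each kind. For the series there are 2 ranked lists, of 56499 and 55701 peaks, a conservative thresholded list of 2522 and a larger one of 2632. The deposited score of each peak is scaled by IDR up to 1000, and no peak of a thresholded list was under 830. The deposited signal is the authors' value of a peak's strength on a scale not given in the sources used here, and it was used only to rank or describe peaks within 1 list. The authors also deposited a −log10 q-value per peak and, in ranked lists, a −log10 IDR and the signals of the matching peaks in 2 input sets. A q-value above 0.05 stood beside 216 conservative peaks. The lists hold no read counts, so depth per sample is unknown, and all intervals cover counting error over peaks or genes only. Since both replicates belong to 1 group, p-values describe peaks and genes of these lists, not a difference between conditions.

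No peak extended past a chromosome end of the reference genome WBcel235, the same assembly as ce11, whose sequence came from RefSeq and whose genes came from Ensembl release 115 with 19973 protein-coding genes. Coordinates are 1-based. Summits were classed, in this order, as promoter proximal (within 500 bp of a protein-coding transcript start), exonic, intronic or intergenic. Null distributions came from 10000 circular shifts of the peaks within each chromosome. The share on X was tested with an exact binomial test.

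Motifs were searched on both strands within 50 bp of the summit, and in flanks from 250 to 300 bp away that held 101 bp in total, as the central window did. Peaks with a motif in only one of the 2 places were compared with an exact McNemar test. As each flank consists of 2 pieces, it holds slightly fewer positions of a motif than the centre, and flanks lengthened to hold as many were added after seeing the data. Ranks of peaks with and without a motif were compared with 100000 permutations. Gene lists were tested with Fisher's exact test on whether a summit lay from 2000 bp upstream to 500 bp downstream of a transcript start, against the 13157 genes with a ranked summit there, of which 1912 (14.5%) were bound. Of the guidance list, 1 gene had no match in the annotation. Tests across several motifs, 6-mers, locations or lists were adjusted by Benjamini-Hochberg where the text calls a p adjusted, every other p is unadjusted, and a threshold of 0.05 was used.

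The 16 gene lists, the 11 motifs and the rule for named genes were fixed before the data were examined. The rule named the gene with the nearest transcript start for the 15 strongest peaks, every member of the Hox and TALE list and of the list of studied targets, and up to 4 bound members of each other list by signal. Alternatives fixed in advance were the larger list, the stronger part of the conservative list, each replicate's list alone, other overlap rules, other distances, windows, flanks and backgrounds. Leaving out peaks of signal under 20 and leaving out peaks near tRNA genes were added after seeing the data. A further 5 classes of widely expressed genes were defined by name for 1 test of the closing section.

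Each step was tested on simulated data with known answers. For motif enrichment, 1 of 220 tests at random positions passed. These random tests used lengthened flanks, so they did not check the main flanks, which hold slightly fewer positions. A site planted in 100 of 2522 windows was found in 20 of 20 sets. For gene lists with 1912 genes drawn as bound, 4 of 800 random tests passed and 37 planted ribosomal protein genes were found in 50 of 50 sets. These genes were drawn independently, whereas real neighbouring genes can share a peak. For overlap, 2 of 20 pairs of random lists passed at an unadjusted 0.05. For summit location, none of 40 random tests passed. For peak strength, 1 of 20 random tests passed. For the 6-mer scan, none of 2080 passed at random positions, and a 6-mer planted in 200 windows ranked first. For the X share and for tRNA genes, none of 20 random sets passed, and 100 peaks moved to X or 50 moved to tRNA genes were found in 20 of 20 sets. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.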

Results

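The series measured where CEH-20 sat on the genome of whole Caenorhabditis elegans larvae in the L4 stage, at 49 hours. CEH-20 is a TALE homeodomain protein of the PBX family, which binds DNA together with Hox proteins and with Meis-type proteins such as UNC-62. The animals carried an eGFP-tagged ceh-20 gene made by CRISPR insertion, and chromatin was pulled down with an antibody against GFP (chromatin immunoprecipitation followed by sequencing, ChIP-seq). The 2 samples were biological replicates of 1 group, so the comparisons were between the replicates, between peaks and their surroundings, and between gene groups. Read depths were not among the values used here. The peak lists held 1249 peaks for replicate 1 and 1490 for replicate 2, while the conservative list drawn from both held 2522 peaks on assembly ce11. These peaks had a median width of 316 bp and covered 762 kb of the genome, which spans 100.3 Mb. Their signal, which is the authors' own value for each peak, had a median of 83.2 and ranged from 2.01 to 735.

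The strongest CEH-20 peaks included several at promoters of ribosomal protein genes. The top peak was on chromosome III at 3867445 to 3867701, between genes and 274 bp upstream of rpl-3, which codes for a ribosomal protein of the large subunit, with a signal of 735. The next, with a signal of 719, lay on the same chromosome at 10759120 to 10759397, 51 bp upstream of tasp-1. A pair of peaks downstream of the start of K08F11.1 on chromosome IV followed, at 680 and 658. The first lay 85 bp from an annotated pseudogene and the second 150 bp from a noncoding RNA gene. Other leading peaks lay upstream of mog-4, an RNA helicase gene (586), of rpl-15 (524), of the Hsp70-family gene F44E5.4 (518), of cdc-48.1, an AAA ATPase gene (509), of rpa-2, a gene for a subunit of the single-stranded DNA binding protein RPA (477), of tos-1 (440) and of rpl-35 (426). A peak of 505 stood between Y17G9B.5 and rpl-20, 175 bp upstream of the first and 287 bp upstream of the second. Further leading peaks lay farther from a protein-coding transcript start. They were 1172 bp downstream of that of F40E3.3 (463), 2586 bp upstream of that of K07D4.2 (446) and 3394 bp downstream of that of Y111B2A.12 (434). The last lay in an intron, and the peak of 446 lay 443 bp from an annotated pseudogene. Each of these 15 peaks was also in the lists of both replicates.

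Loci of the Hox and TALE homeobox genes themselves were bound. A gene was called bound when a summit lay from 2000 bp upstream to 500 bp downstream of one of its transcript starts. By that rule 6 of the 9 list members with any ranked peak were bound (66.7%, exact 95% interval 29.9 to 92.5), against 14.5% of the other genes, an odds ratio of 11.8 (Fisher's exact test, two-sided, adjusted p = 0.00423 over 16 lists). The odds ratio was 20 with the larger list and 19.1 with that of replicate 2 alone. The 6 genes were psa-3 and unc-62, which code for Meis-type partners, the Hox genes ceh-13, lin-39 and nob-1, and ceh-20. The psa-3 peak, in an intron just upstream of a transcript start (chromosome X, 15408662 to 15408977), had a signal of 179. The ceh-20 gene had a peak of 168 on chromosome III at 6978993 to 6979308, 733 bp upstream of its start. The nob-1 peak (chromosome III, 12084783 to 12085098) had a signal of 149 and lay 625 bp upstream. At unc-62 a peak of 101.3 lay in the 5' UTR on chromosome V, 58 bp from a start, and a stronger one of 165 lay in the 5' UTR 1109 bp downstream of a start. These peaks were in the lists of both replicates, apart from that at lin-39.

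Within 53.4 kb around lin-39 and ceh-13 on chromosome III the conservative list held 7 peaks, the list of replicate 1 held 2 and that of replicate 2 held 3. Of the 7, 1 had a signal of only 4.44 and overlapped a peak of 75.7. The ceh-13 peak (7554727 to 7555042) lay 775 bp upstream of the gene with a signal of 124 and was in the lists of both replicates. The lin-39 peak (7534589 to 7534904) lay in the 5' UTR, 58 bp downstream of a start, with a signal of 82.6, and was in the list of replicate 2 but not in that of replicate 1. The posterior Hox genes egl-5 and php-3 and the PBX genes ceh-40 and ceh-60 were not bound by the rule, nor was the Hox gene mab-5. A peak of 66.1 lay in an intron of mab-5, 2824 bp downstream of its start, and a peak of 73.9 in the coding sequence of ceh-60.

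**Figure D1:**
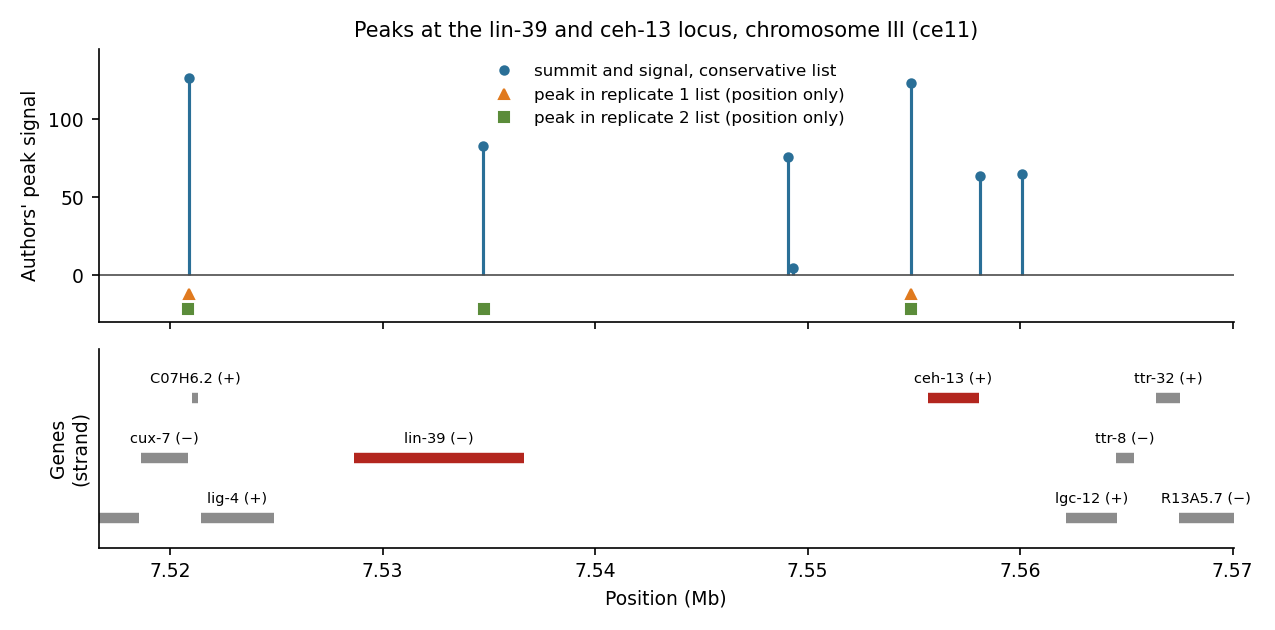
The authors' signal (vertical axis, no unit given) of the 7 conservative peaks is drawn at their summits over the lin-39 and ceh-13 locus of chromosome III (horizontal axis, Mb, ce11), with markers for peaks in the replicates' lists and protein-coding genes below. The ceh-13 promoter peak, at 124, has markers from both replicates, and the lin-39 peak, at 82.6, has 1 from replicate 2.

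Genes studied before as targets of Hox and PBX proteins were less clearly set apart. Of 8 such genes with a ranked peak, 4 were bound (50%, exact 95% interval 15.7 to 84.3), namely ceh-13, lin-39, psa-3 and the guidance gene mig-13 (56.2), and the first 3 of these were also members of the Hox and TALE list. The share missed the threshold (Fisher's exact test, adjusted p = 0.102 over 16 lists), although it passed with circular shifts of the peaks in place of a gene background (permutation, adjusted p = 0.0405) and when a peak was given only to its nearest transcript start (Fisher's exact test, adjusted p = 0.0246). In the list of replicate 1 the share was 25% of the 8 genes and in that of replicate 2 it was 37.5%, with mig-13 bound in neither. The Twist gene hlh-8, the cell death gene egl-1, the Wnt gene egl-20, the GATA genes egl-18 and elt-6, and sem-2 had no conservative peak in their windows.

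Ribosomal protein genes formed the other group that was bound more often. Of 75 with a ranked peak, 40 were bound (53.3%, exact 95% interval 41.4 to 65.0) against 14.3% of the other genes, an odds ratio of 6.84 (Fisher's exact test, adjusted p = 5.44e-14). By the nearest transcript start it was 25 of 70, an odds ratio of 3.61. Their strongest members were rpl-3, rpl-15, rpl-20 and rpl-35. No other list passed the threshold. Cuticle collagens were at 11 of 134 (8.21%, Fisher's exact test, adjusted p = 0.143), led by col-94 at 275, whose peak lies in an intron of dhc-4, col-185 at 130, col-85 at 117 and col-72 at 104. With the larger list of 2632 peaks their lower share did pass (Fisher's exact test, adjusted p = 0.0112), whereas against circular shifts it was higher, at 8.21% against 5.61% (permutation, adjusted p = 0.562). Wnt signalling genes were at 6 of 23, with mig-5, a Dishevelled gene, at 178, mom-5 at 82.9, cam-1 at 76.0 and kin-19 at 74.9. The mom-5 peak lay 1882 bp from its start and 1715 bp from that of algn-10. Genes of neuronal function were also at 6, of 25, led by unc-64 at 88.4, egl-3 at 88.2, rab-3 at 79.1 and ida-1 at 76.4. Both lists passed only with the nearest transcript start (Fisher's exact test, adjusted p = 0.0339 and 0.0246).

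The remaining lists did not pass, and their bound members are given as values. Muscle structure genes were at 4 of 27, which were dim-1 (91.4), unc-97 (77.4), act-4 (74.6) and unc-60 (68.8). None of these had a peak in its window from the list of replicate 2. Vulval genes were at 2 of 15, with egl-17, an FGF gene, at 149, beside lin-39. Intestinal genes were at 2 of 16, the GATA gene elt-2 at 78.6 and the vitellogenin gene vit-2 at 40.7. Guidance genes were also at 2 of 16, unc-5 at 76.1 and mig-13. Germline genes were at 2 of 20, cgh-1 at 120 and rad-51 at 70.5. The cgh-1 peak lay 764 bp from its start and 742 bp from that of C07H6.9. The M lineage of the postembryonic mesoderm had 1 bound gene of 9, sma-9 at 173, and regulators of seam and epidermis 1 of 17, lin-28 at 87.9. Histone genes were at 6 of 37, where his-35 and his-37 shared a peak of 416 and his-67 and his-68 a peak of 85.2. All homeobox genes together were at 11 of 65, including ceh-38 at 151. None of 13 major sperm protein genes was bound, which allows a share of up to 24.7% (upper bound of the exact 95% interval). Of all 62 genes named by the preset rule, 49 were bound and 27 of these had a peak in the lists of both replicates. Many were named because they were bound or lay nearest a strong peak, so 49 of 62 is not a rate of binding. The window peaks of elt-2, ida-1, kin-19, mig-13, unc-60 and unc-97 were in the list of neither replicate.

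**Figure D2:**
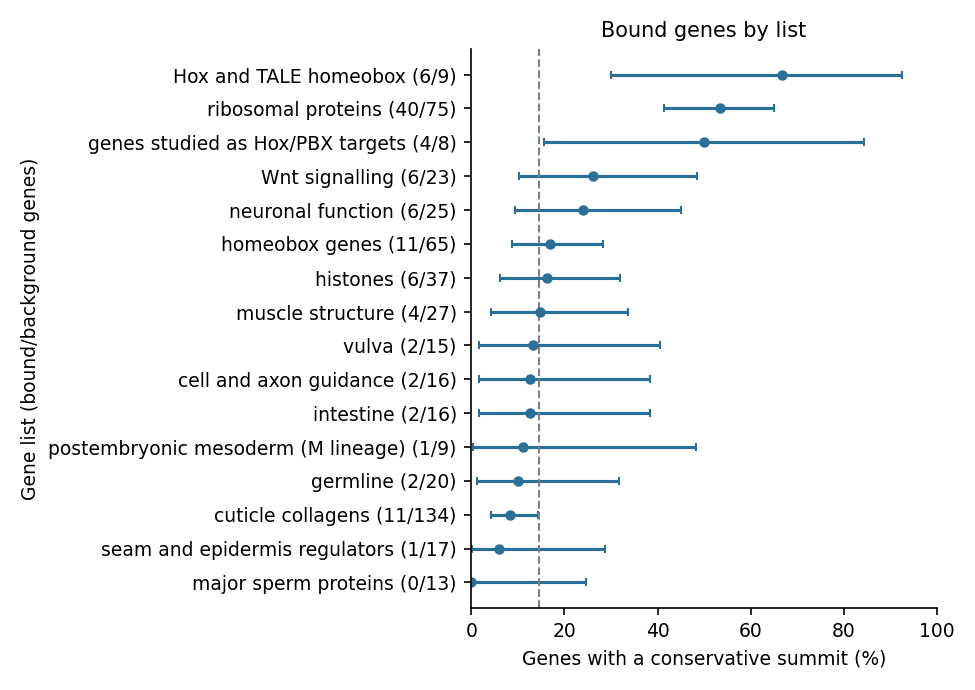
Points show the percentage of each list's background genes with a conservative summit in their window, bars the exact 95% interval, and the dashed line the 14.5% of all background genes. The intervals of ribosomal proteins, the Hox and TALE list and the studied targets lie wholly to the right of the line, and that of the cuticle collagens wholly to the left.

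Many peaks also lay near transfer RNA genes. Control libraries and other factors were not analysed here, so a signal common to many ChIP experiments stays open for them. Of the 2522 summits, 225 lay within 200 bp of a tRNA gene (8.92%, exact 95% interval 7.84 to 10.1), and 236 of the 612 annotated tRNA genes had such a summit. Peaks shifted along their chromosomes reached a mean of 0.311% and at most 1.43% (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give).

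Most peaks lay near promoters or between genes, and few in exons. Summits within 500 bp of a protein-coding transcript start made up 38.9% of the list (exact 95% interval 37.0 to 40.8) against 22.6% ± 0.893 (SD over 10000 shifts) after shifting. Intergenic summits were at 37.6% against 30.2%. Exonic summits were at 4.28% against 20.7%, and intronic summits at 19.2% against 26.5% (two-sided permutation, adjusted p = 0.0002 for all 4 locations, the smallest that the shifts can give). The median distance to the nearest transcript start was 859 bp, 69.5% of summits lay upstream of it, and 73.3% were within 2000 bp. Compared with the 53977 ranked peaks outside the list, the odds of a promoter location were 1.90 times as high (Fisher's exact test, unadjusted p = 9.42e-50).

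The X chromosome held more than its part of the peaks. It carried 630 of the 2522 (25%, exact 95% interval 23.3 to 26.7), while it makes up 17.7% of the genome (exact binomial test, two-sided, p = 4.52e-20) and held 18% of the 56499 ranked peaks (exact binomial test, p = 1.74e-18). That came to 35.6 peaks per Mb on X and 22.9 on the autosomes, a ratio of 1.55. Chromosome V had the lowest density, with 18.7 peaks per Mb. Among the 631 strongest peaks X held 21.9% (exact 95% interval 18.7 to 25.3), and among the 630 weakest 27.6% (24.2 to 31.3).

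**Figure D3:**
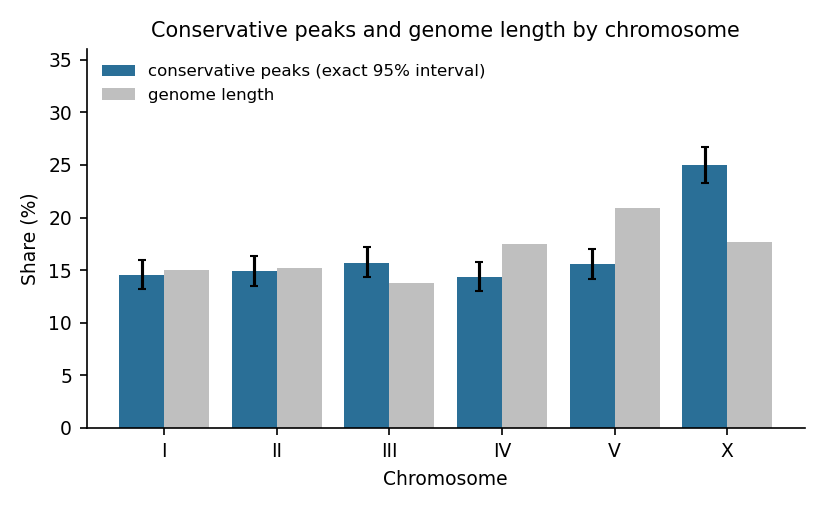
Dark bars give each chromosome's share of the 2522 conservative peaks (percent, with exact 95% intervals) and light bars its share of the genome. X stands at 25% of peaks and 17.7% of the genome.

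Sequences known for PBX proteins were more frequent at the summits than beside them. The PBX-Hox composite site TGATNNAT lay within 50 bp of the summit in 256 peaks (10.2%, exact 95% interval 9 to 11.4) and in flanks of the same total length 250 bp away in 194 (7.69%), a ratio of 1.32 (exact McNemar test, two-sided, adjusted p = 0.00430 over 11 motifs). Among the 1261 strongest peaks it was in 141 against 82 flanks, while in the next 630 it was at 9.21% against 9.37% and in the 630 weakest at 9.05% against 8.41%. The PBX-Meis composite TGATTGAC was rare, with 19 peaks against 4 (exact McNemar test, adjusted p = 0.00430). It did not pass against shuffles of the same windows that kept their dinucleotides, where the ratio was 2.11 (exact McNemar test, adjusted p = 0.137), nor in the 1261 strongest peaks. In the lists of single replicates it was in 9 peaks against 1 and in 13 against 1. At least 1 of the composites was present in 273 peaks (10.8%). The scrambled PBX-Hox control fell, from 4.28% in flanks to 2.58% at summits (exact McNemar test, adjusted p = 0.00275). The control thus also passed the threshold against flanks, in the opposite direction. Against shuffles its ratio was 1.44 (exact McNemar test, adjusted p = 0.123) where that of the composite was 1.61. Within 25 bp of the summit its fall did not pass (ratio 0.756, exact McNemar test, adjusted p = 0.397). Peaks with and without the PBX-Hox composite had mean ranks by signal of 1223 and 1266 (permutation test, adjusted p = 0.748). Within the 1261 strongest peaks the difference turned, and those with the site ranked 70.5 places lower on average (permutation test, unadjusted p = 0.0304).

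Motifs of other factor families also differed between summits and flanks. The Meis core TGACAG was at 4.88% against 2.38%, but at 0.831 times its frequency in shuffled windows. The E-box CACGTG was at 5.43% against 1.39%, a ratio of 3.91, and GAGAGA at 22.3% against 7.30%, a ratio of 3.06 (exact McNemar tests, adjusted p = 1.00e-15 and 1.19e-52). Against shuffled windows these ratios were 2.49 and 2.04. The TCF core TCAAAG fell from 8.21% to 4.76% (exact McNemar test, adjusted p = 3.12e-06). GATA sites were at 22.6% against 20.3% (exact McNemar test, adjusted p = 0.0618); they passed against shuffles, at a ratio of 1.64, within 25 bp, at 1.29, and without peaks near tRNA genes, at 1.16, and fell to 0.957 in the 1261 strongest peaks. The Twist-type E-box CATATG and the AP-1 site TGASTCA did not pass (exact McNemar tests, adjusted p = 0.332 and 0.108). The central windows were richer in G and C (46.6%) than the flanks (35.3%).

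A scan of all 6-mers gave 816 of 2080 as more frequent at summits and 414 as more frequent in flanks (exact McNemar tests, adjusted over the 6-mers). The leading ones were CGTCTC, AGAGAG, GAGAGA, ACGCAG, GACGCA, AGAGAC, AGACGC, CGCAGA, CCTCTC and ACGAGA. CGTCTC was present in 388 peaks (15.4%) and in 61 flanks, a ratio of 6.36 (exact McNemar test, adjusted p = 1.04e-58). Several of these overlap in the 8-mer AGACGCAG, which was in 184 peaks and 18 flanks, a ratio of 10.2. The 6-mers that fell most at summits were runs of A and T, led by AAAATT. The scan was not run against shuffled windows, so the difference in G and C between summits and flanks was not taken out of these counts.

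**Figure D4:**
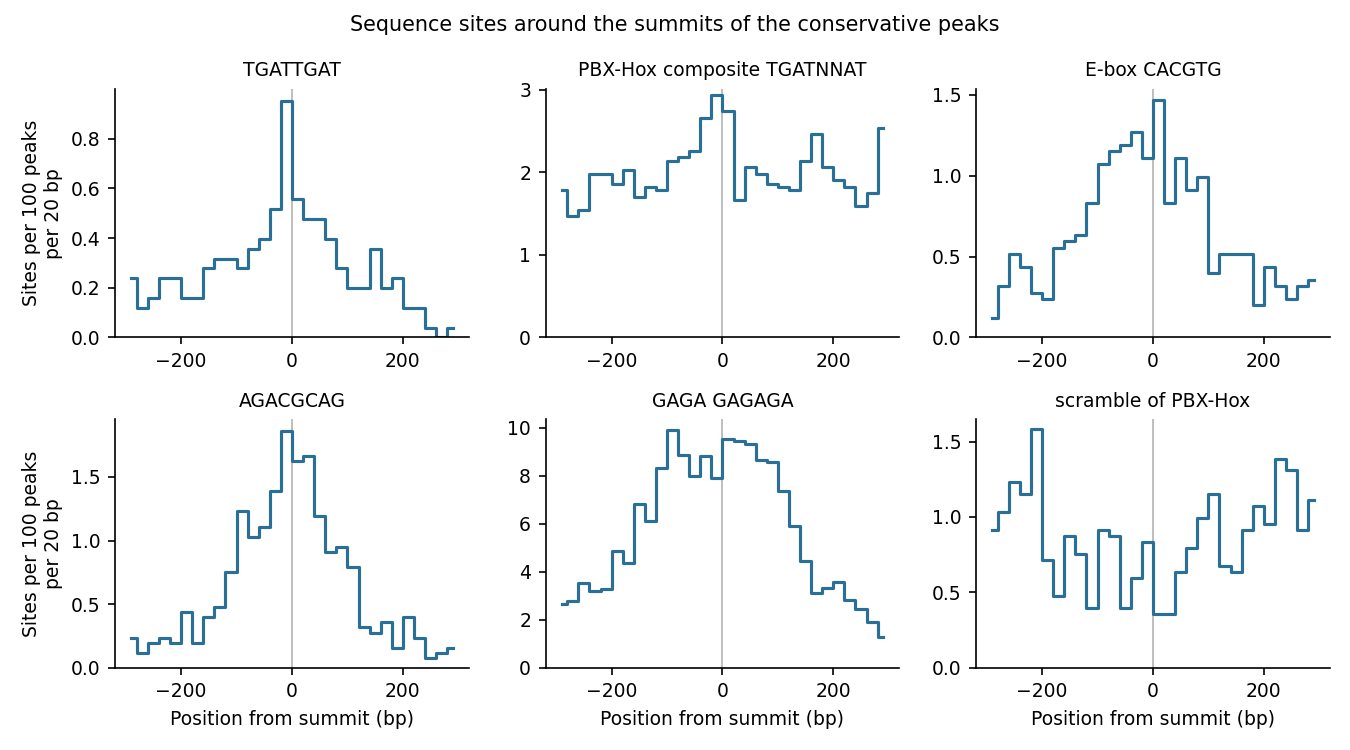
Each panel gives sites per 100 peaks in bins of 20 bp (vertical axis, with a scale of its own starting at 0) by distance from the summit (horizontal axis, bp) for 1 sequence, over 2522 peaks. All but the scrambled control are highest within about 100 bp of the summit.

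The replicates shared most of their strong sites. Of the replicate 1 peaks, 855 of 1249 overlapped a replicate 2 peak by at least 1 bp (68.5%, exact 95% interval 65.8 to 71.0), and 854 of 1490 the other way (57.3%, 54.8 to 59.8). Shifted peaks overlapped in 0.815% and 0.680% (one-sided permutation p = 0.0001 for both, the smallest possible). Shared peaks had a median signal of 68.3 and the others 50 in replicate 1, and 64.1 against 44.8 in replicate 2. Of the 394 replicate 1 peaks not shared, 367 (93.1%) overlapped a peak in the ranked list of replicate 2, which has no threshold, as did 608 of 636 (95.6%) the other way. The ranked lists of replicates 1 and 2 held 40237 and 36837 peaks, with summed widths of 11413 and 10296 kb. The overlap of shifted peaks with them was not computed. Of the conservative peaks, which were called on both samples pooled while the replicates' lists were called per sample, 860 (34.1%) were in both replicates' lists, 316 only in that of replicate 1, 470 only in that of replicate 2, and 876 (34.7%) in neither. Across the 2522 conservative peaks, which are not independent, the signals of both input peak sets had a Spearman rho of 0.570 and a Pearson r of 0.757 on log10 values. These peaks were selected by the agreement of their ranks, and over all 56499 ranked peaks the values were 0.313 and 0.499. The larger list shared 2178 of its 2632 peaks (82.8%) exactly with the conservative one, and 84.7% of its peaks overlapped a conservative peak. It did not contain the conservative list, of which 344 peaks had no identical peak in it.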

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

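The test of higher coverage of X and that of tissue classes were chosen after the result was seen; the other tests of explanations were set before. The design has 1 group, so no difference between groups was there to set against these explanations.

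The ranked list of the series held 30 peaks that reached the lowest score of the conservative list, 830, and were absent from it. They entered the report only within the totals of ranked peaks. The strongest ranked peak of all was among them. It lay on chromosome X at 15810939 to 15811167, 858 bp from an annotated pseudogene, and its signal of 1643 was 2.24 times that of the strongest peak kept. Others clustered on chromosome I near 10947400, on chromosome IV near 10945697 and on chromosome V at 17122016, beside the 5S rRNA gene rrn-4.2. Repeated sequence is a candidate explanation. The median share of 36-base sequences around these summits that occur more than once in the genome was 79.5%, against 0% for the kept peaks, and the share was over 50% in 22 of the 30 and in 151 of the 2522 (Fisher's exact test, p = 1.92e-20). Of 4 peaks with no repeated sequence, 2 had a deposited IDR above 0.01, as no kept peak did, and the absence of the other 2 stays open.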

How the results depend on the processing

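Leaving out peaks of signal under 20, leaving out peaks near tRNA genes and the lengthened flanks were chosen after seeing the data; the other alternatives were set before. Replicate overlap (52.7 to 71.6%), the X share (22.1 to 24.6%), the tRNA share (8.96 to 10.8%) and all 4 summit locations kept their direction and stayed past the threshold under every alternative run. So did the PBX-Hox composite, whose ratio was 1.20 within 100 bp, 1.22 with lengthened flanks, 1.61 against dinucleotide shuffles and 2.25 within 25 bp. The PBX-Meis composite lost the threshold in the 1261 strongest peaks, where its ratio was 8 on 8 peaks, and against shuffles, at 2.11, and was 9 to 13 without one replicate. Against shuffles the Meis core turned to 0.831 and the PBX-Hox scramble to 1.44, neither past the threshold. The rank difference of peaks with the PBX-Hox composite, -43.0 in the whole list, turned to 70.5 in the 1261 strongest (permutation p = 0.0304), to 17.7 within 100 bp and to 5.68 to 55.8 without one replicate. That of the PBX-Meis composite, 32.7, turned to -97.7 in the strongest, to -34.6 without peaks of signal under 20 and to -62.6 to -3.22 without one replicate. The cause was not tested for any of these. The Hox and TALE and ribosomal protein lists passed under all 10 alternatives, and 5 lists passed with the nearest transcript start. Further results, passing neither in the main analysis nor under the alternative named here, changed direction. For motif ratios these were GATA at 0.957 in the strongest peaks and 0.953 to 0.971 without one replicate, the Twist-type E-box at 1.05 to 1.10 without one replicate and 1.29 within 25 bp, and AP-1 at 0.900 against shuffles. GATA passed at 1.29 within 25 bp, 1.64 against shuffles and 1.16 without tRNA peaks. For list differences in percentage points they were histones at -4.12 with the larger list; M lineage at 2.59, muscle at -4.83, Wnt at -4.19 and neuronal at -0.529 in the strongest peaks; without one replicate, M lineage at 1.58 to 3.22, muscle at -9.55 to -0.483, vulva at -1.22 to 3.81, seam at -7.90 to 2.24, germline at -7.90 to 0.470, Wnt at -3.55 to 7.87 and neuronal at -3.90 to 6.48, the last 5 in only 1 of the replicates; muscle at -1.19, vulva at 3.95 and intestine at 1.56 with 1000 bp upstream. They were also M lineage at 6.54, seam at 10.1 and guidance at 1.54 with the nearest start, intestine at 2.19 against all protein-coding genes, and M lineage at 2.15, vulva at 6.27, collagens at 2.59, intestine at 6.35, guidance at 1.74 and germline at 4.13 against circular shifts. Of the 62 named genes, 17 had no peak in the window from the replicate 1 list and 11 from the replicate 2 list while bound in the conservative one. The 6-mer count ranged from 599 to 831, and 937 of 32896 8-mers passed. No paired analysis was possible because the series has 1 group. Depth was not among the values used here, so sites below the calling limit of either replicate cannot be separated from absent sites.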

Other observations

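All values of this part were chosen after the data were seen, apart from the tests of tRNA genes, of transcript starts on X, of the PBX-Hox sequence and of 5 gene classes, which were set before their results were seen.

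Within the PBX-Hox composite the sites were unequal. Of the 16 forms of its free bases, TGATTGAT was at the summit of 70 peaks and in the flank of 10, a ratio of 7 (exact McNemar test, adjusted p = 5.06e-11 over the 16 forms), TGATTTAT of 51 and 19 (exact, adjusted p = 0.00105) and TGATGGAT of 24 and 7 (exact, adjusted p = 0.0106), while TGATTCAT (4 and 21) and TGATATAT (4 and 20) were more frequent in flanks (exact, adjusted p = 0.00486 and 0.00618). The strongest peak with TGATTGAT, at rank 17 with a signal of 419, was intergenic on chromosome X at 11094047 to 11094342, 3996 bp from the start of W02H3.3. Others lay 177 bp from F54C9.3 (242), 876 bp from the nuclear receptor gene nhr-40 (195), 1273 bp from the fatty acid desaturase gene fat-1 (138) and 8424 bp from the Toll receptor gene tol-1 (138). Of the 70 peaks, 24 were on X and 1 was near a tRNA gene. The site lay a median of 18 bp from the summit. The 184 peaks with AGACGCAG included F44E5.4 (518), drr-2 (383) and sec-61.G (344), and none of them was near a tRNA gene.

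A scan of 128 gene name classes with at least 10 background genes gave 5 as bound more often and 3 as bound less often (Fisher's exact tests, adjusted over the 128). Besides rps (19 of 28) and rpl (23 of 46), these were hsp, the heat shock genes (10 of 18, exact test, adjusted p = 0.00185), unc, named for uncoordinated movement (25 of 78, adjusted p = 0.00185), and lin, named for cell lineage (14 of 41, adjusted p = 0.0282). Lower were clec, the C-type lectins (4 of 141, exact test, adjusted p = 0.000251), fbxa, F-box genes (4 of 97, exact test, adjusted p = 0.0369), and str, chemoreceptors (1 of 59, exact test, adjusted p = 0.0373). Genes with more transcript starts have more windows, which these tests did not take out. Circular shifts, against which the lower share of collagens turned, were not run for the name classes. Small nucleolar RNA genes also had summits within 200 bp, 71 of 346 genes with 2.82% of peaks against 0.176% for shifted peaks, as did small nuclear RNA genes (0.674% against 0.0576%) and microRNA genes (0.397% against 0.125%; permutation, adjusted p = 0.0002, 0.0002 and 0.00405, where 0.0002 is the smallest reached). Long intergenic noncoding RNA genes were at 0.634% against 0.316% (permutation, adjusted p = 0.0184). None of 20 rRNA genes had a conservative summit, though a ranked peak left out of that list, with a signal of 81.5, lay beside rrn-4.2.

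The peaks at ribosomal protein genes (median signal 130) and tRNA genes (88.7) may reflect recruitment or retention without the PBX-Hox sequence. The composite was within 50 bp of the summit in 5 of 263 such peaks (1.90%) and in 11.1% of 2259 others, an odds ratio of 0.155 (Fisher's exact test, 95% interval 0.0495 to 0.372, p = 6.87e-08), but GAGAGA (11.4% against 23.6%) and AGACGCAG (0.380% against 8.10%) were rarer there too, although at the 38 ribosomal protein peaks alone only the composite passed (in none, 4 and 1 of them, Fisher's exact tests, p = 0.0281, 0.113 and 0.521). Collagen, muscle and sperm protein genes together were bound in 8.62% (upper bound 13.8%) against 14.6% of others, but 134 of these 174 genes were collagens. Muscle genes alone had an upper bound of 33.7%. As no expression was measured, high expression in some tissues stays open. Expression in all tissues stays open, as 5 other widely used classes were bound in 22% of their genes against 14.4% of others (Fisher's exact test, adjusted p = 0.0278), where only translation factors passed alone (14 of 38, Fisher's exact test, adjusted p = 0.00389), with the proteasome at 5 of 29, the mitochondrial ribosome at 11 of 54, the vacuolar ATPase at 5 of 19 and aminoacyl-tRNA synthetases at 2 of 28. Control libraries and other factors were not analysed here, so a signal common to many ChIP experiments stays open too.

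Annotated tRNA genes were concentrated on X (276 of 612), and so were the peaks near them (102 of 225), yet they could account for the X excess only in part. Without those peaks X still held 23% (exact 95% interval 21.3 to 24.8) against 17.7% of the genome. The layout of promoters is argued against as the whole cause, as 20.1% of promoter-proximal peaks lay on X against 14.3% of promoter-proximal bases (exact binomial test, p = 7.93e-07). X held 18% of all ranked peaks (exact 95% interval 17.7 to 18.3). That share counts peaks and does not measure coverage, and depth was not among the values used here, so higher coverage of X stays open. What raised the share on X stays open; sequence differences between the tagged strain and the reference were not tested.

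The conservative list also held 134 peaks (5.31%) of signal under 20, each with a q-value above 0.05. Of these, 127 overlapped a conservative peak of higher signal, at a median distance of 202 bp between summits.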
